A study of Homo sapiens with 6 samples.

How the data were processed

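The labels describe HEK293 lysate digested with micrococcal nuclease, pooled and divided over immunoprecipitations with an antibody to HuR or with normal mouse serum, 3 samples of each. The 3 HuR samples were grouped and numbered by their titles. Per the submitters' processing notes, cutadapt 1.0 and TopHat2 2.0.8 were used, with the genome build hg19 (GRCh37). The deposited lists give a LOD score per interval, computed by the authors, and the way intervals and scores were made is not given in the sources used here. Intervals end on a grid of 5 nt. Per the names of the deposited lists, all intervals have a LOD score above 0 and 1 combined list was further limited by the authors at p 0.05. The values themselves were checked and all were above 0. The discrete score levels are spaced differently in each list, so scores were not compared in size between lists, except for the LOD difference recomputed in the p-filtered list, whose size is not on a known common scale. Pearson coefficients use the scores as given and do not depend on a linear scale, while the thresholds of LOD above 1 and above 2, applied to every list, need not be equally strict in each. Read counts and depth per library are unknown, and no intervals that need them are given.

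Sites of each list were compared on the same strand with bedtools 2.31.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. An overlap of at least 1 nt counted as a match, and a control set was made by shifting sites by 500, 1000 and 5000 nt. Bases called in 1, 2 or 3 replicates were counted, and combined sites were sorted by the number of replicate lists they overlapped. Pearson and Spearman coefficients were computed across shared sites. Each site was paired with the overlapping site that shared the most bases, and ties went to the higher score. Chromosome ratios used the end of the last site as length. The code was tested on simulated data of 658853 sites, where the largest error in a Pearson coefficient was 0.00208. Matched simulated sites had identical coordinates, so the pairing of partly overlapping sites was not tested. Coordinates are 1-based on hg19.

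The designs of these comparisons, their score thresholds, overlap alternatives and leave-one-out alternatives were chosen before the data were examined. Strand shares, neighbours, chromosome ratios, score deciles, opposite-strand overlap, mitochondrial sites, site widths, X and Y partners and the 10-kb window size were chosen after seeing the data. For bases called in all 3 replicates, stability was first judged against the spread between replicates' shares, under which every alternative counted as unmoved. That yardstick was replaced, after its outcome was seen, by the 95% Wilson interval of the share. This interval covers counting error only and treats adjacent bases as independent, so it is too narrow for an alternative to stay within it. The rule for named items, written for genes, takes the 10 highest combined scores at sites found in all 3 replicates and the 10 places with the most bases in all 3. It was applied to sites and windows, because the lists carry no gene names and the annotation at hand is on another build, which was not mixed with hg19. For the same reason 6 planned results on transcript regions, sequence composition and 14 gene lists were not run. Not every item that the rule takes is named.

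Of the explanations weighed in the closing section, those for low-scoring sites were added after a first set of tests had been run. That first set also tested explanations for opposite-strand overlap and for sites shared by chromosomes X and Y, which are now given as values only.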

Results

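The study mapped RNA bound by HuR, the ELAVL1 protein, in HEK293 cells, an established human embryonic kidney line. HuR is an RNA-binding protein known to bind U-rich and AU-rich RNA. In DO-RIP-seq, lysate was digested with micrococcal nuclease, RNA fragments were recovered with an antibody to HuR, and the fragments were sequenced. The labels list 3 HuR immunoprecipitations and 3 negative control immunoprecipitations with normal mouse serum. The files analysed here hold 1 list of HuR sites for each HuR replicate and 2 lists for the 3 replicates combined, and the negative control samples were not analysed here as separate values. Each site is a stretch of 1 strand of hg19 with the authors' LOD score above 0. The score's scale and log base are not given in the sources used here, and its levels differ between lists, so the size of a score in 1 list is not compared with that in another, although correlations and common score thresholds use the scores as given. Read depth per library is unknown. The digested lysates were pooled before they were divided over the immunoprecipitations, per the labels' protocols. If 1 pool served all samples, the replicates share cells and digestion, and each SD with n = 3 covers technical spread only.

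HuR sites covered between 9.14 and 31.8 Mb of strand-specific sequence per replicate. Replicate 1 had 186157 sites, replicate 2 had 405048 and replicate 3 had 550681, a mean of 380629 ± 183485 (SD, n = 3). The list with the most sites had 2.96 times as many as the list with the fewest. Sites were short in every replicate, with median widths of 45, 55 and 50 nt, a mean of 50 ± 5 nt (SD, n = 3). The plus strand carried 51.0%, 50.8% and 50.8% of the sites in replicates 1, 2 and 3. Neighbouring sites on a strand lay close together, with median gaps of 855, 455 and 425 nt in the same order.

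The first comparison asked whether HuR was found at the same places in each replicate. Most sites of the smaller list of each pair overlapped a same-strand site of the larger list by at least 1 nt, with 92.7% for replicates 1 and 2, 92.1% for replicates 1 and 3 and 85.8% for replicates 2 and 3. The mean was 90.2% ± 3.80 (SD over 3 pairs, which share replicates and are not independent). After sites were shifted by 500 nt along the strand, 23.3%, 24.1% and 22.6% overlapped, so the observed overlap was 3.98, 3.82 and 3.80 times the highest shifted value. In the other direction, 39.2% of replicate 2 sites and 29.3% of replicate 3 sites overlapped a replicate 1 site. The overlap was lower when each list was limited to its 186157 highest-scoring sites, with 67.5%, 55.6% and 69.7% for the same 3 pairs. Over bases, the Jaccard index was 31.9% for replicates 1 and 2, 25.8% for replicates 1 and 3 and 56.6% for replicates 2 and 3.

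Bases called in all 3 replicates formed a small part of the sequence called in any replicate, though most of what replicate 1 allowed. Of the 37.5 Mb called in any replicate, 42.2% was called in 1 replicate, 36.0% in 2 and 21.8%, or 8.18 Mb, in all 3. Replicate 1 covered 9.14 Mb, the most that could be called in all 3, and 89.5% of its bases were. Without replicate 1, 56.6% of the bases called in replicate 2 or 3 were called in both. Of the replicate 1 sites, 165939 (89.1%) overlapped a site in both other replicates, against 153150 (37.8%) for replicate 2 and 156190 (28.4%) for replicate 3. With the 186157 highest-scoring sites of each list the shares were 50.4%, 46.8% and 47.0%. The counts overlapped in both others are similar from each side, so lists of equal size give similar shares by construction. The nearness of these shares therefore says nothing on the contrast, while the replicate 1 share fell from 89.1% to 50.4%. With at least 50% of each interval shared, and all sites of each list, the shares were 53.0%, 25.8% and 19.3%. Sites seen in no other replicate numbered 8133 (4.37%) in replicate 1, 51703 (12.8%) in replicate 2 and 192719 (35.0%) in replicate 3.

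**Figure D1:**
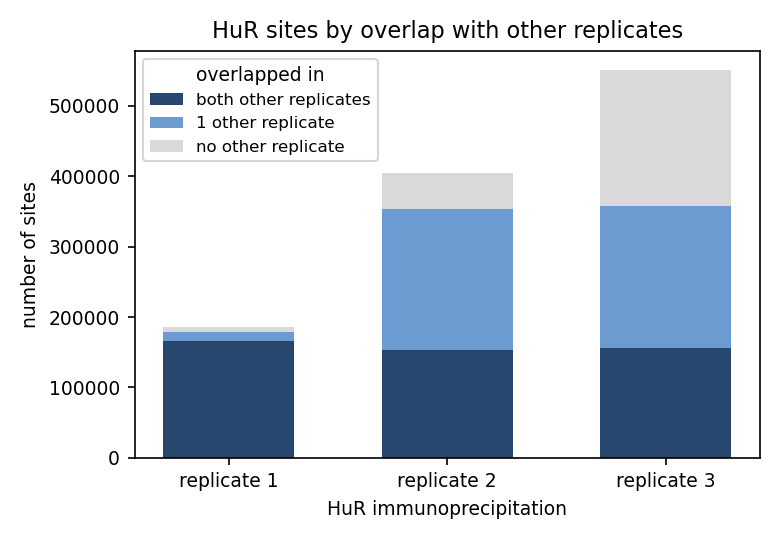
Number of HuR sites (vertical axis) in each of the 3 HuR immunoprecipitations, with bars divided by how many other replicates held an overlapping site. The part overlapped in both other replicates is of similar height in all bars (165939, 153150 and 156190 sites), while the part overlapped in no other replicate runs from 8133 sites in replicate 1 to 192719 in replicate 3.

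High-scoring HuR sites recurred more often than low-scoring ones, but the relation was not a steady rise. In the top score decile, 99.4% of replicate 1 sites, 93.0% of replicate 2 sites and 73.8% of replicate 3 sites overlapped a site in both other replicates, a mean of 88.7% ± 13.4 (SD, n = 3). In the bottom decile the values were 65.8%, 24.2% and 26.5%, a mean of 38.8% ± 23.3 (SD, n = 3). The difference was 49.9 ± 17.7 percentage points (SD, n = 3) and was positive in every replicate. Top-decile sites were also wider, with medians of 60, 85 and 75 nt against 30, 40 and 35 nt in the bottom decile. Among sites of 30 to 40 nt the difference was 27.8, 72.0 and 15.4 points in replicates 1, 2 and 3, a mean of 38.4 ± 29.8 (SD, n = 3). Few top-decile sites had this width, with 1511, 563 and 2324 in the same order. They recurred at 96.4%, 87.7% and 34.9%, so in replicate 3 far less often than its top decile as a whole. In replicates 2 and 3 the lowest values lay in the third decile, at 12.9% and 8.77%, below those of the bottom decile. An exact two-sided sign-flip test over 3 replicates cannot give p below 0.25, so no p-value is given.

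**Figure D2:**
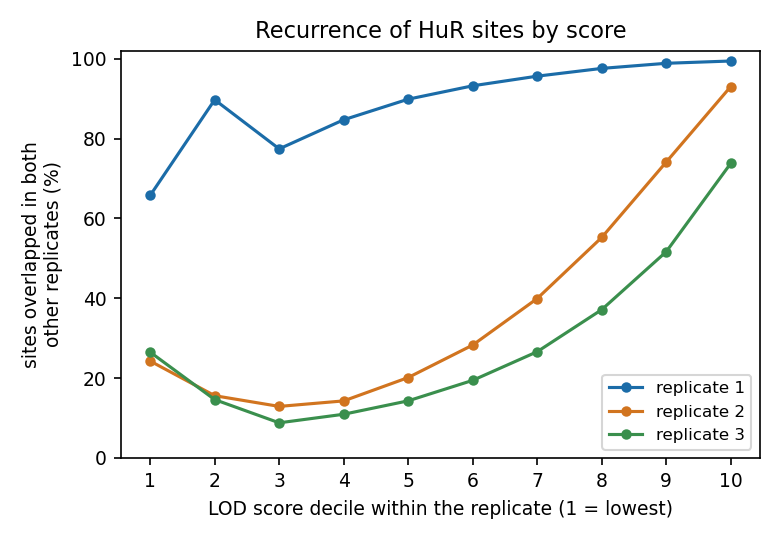
Percentage of HuR sites overlapped in both other replicates (vertical axis) by LOD score decile within each replicate (horizontal axis, 1 lowest), with a line per replicate. Replicates 2 and 3 fall from 24.2% and 26.5% in the bottom decile to 12.9% and 8.77% in the third and then climb to 93.0% and 73.8%.

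Scores of shared sites were correlated between replicates. Across the 172574 sites shared by replicates 1 and 2, Pearson's r was 0.602 and Spearman's rho 0.570. Across 171389 sites shared by replicates 1 and 3 the values were 0.561 and 0.522, and across 347618 sites shared by replicates 2 and 3 they were 0.704 and 0.658. The mean r was 0.622 ± 0.0735 (SD over 3 pairs). These are correlations across sites, which are not independent replicates, and only sites above 0 in both lists entered.

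The combined list asked which sites stood out when the 3 HuR replicates were scored together. It held 658853 sites. The 150603 sites (22.9%) overlapping all 3 replicate lists had a median LOD of 11.2 and a median width of 85 nt. The 197652 sites in 2 lists had a median LOD of 7.76, and the 238328 in 1 list had 5.04. A further 72270 sites overlapped no replicate list and had a median LOD of 3.12 and a median width of 25 nt. The combined list contains the replicates' reads, so its scores and their recurrence are not independent.

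The authors' p filter kept nearly every site found in all 3 replicates and fewer of the others. A p-filtered interval was present in 344635 combined sites, or 52.3% (95% Wilson interval 52.2 to 52.4, counting error only). The filter kept 98.1% of the sites found in all 3 replicates, 66.6% of those in 2, 24.2% of those in 1 and 10.4% of those in none. By combined score, the kept share was 6.40% in the lowest quintile and 95.9% in the highest. The filter also trimmed sites: 45.3% of the bases were kept, and 17.4% of the kept sites had unchanged ends.

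The strongest sites found in all 3 replicates lay on several chromosomes. The highest combined LOD, 30.4, was at chromosome 2:109683536-109683565 on the minus strand, where the replicate scores stood at the 99.9 ± 0.0993 percentile of their lists (SD, n = 3). Chromosome 3:197679666-197679740 on the plus strand had a combined LOD of 28.5, and chromosome 7:72829176-72829240 on the minus strand had 28.4. Chromosome 1:155889591-155889685 on the minus strand reached 27.9, chromosome 11:63962531-63962610 on the plus strand 27.6, and chromosome 10:21769586-21769620 on the minus strand 27.4. At chromosome 7:151687661-151687690 on the minus strand the combined LOD was 28.3, with replicate scores of 15.4, 9.45 and 3.65, and the replicate 3 score stood only at percentile 43.9. At chromosome 6:162058741-162058770 on the minus strand, also at 28.3, the replicate 3 score stood at percentile 73.0. Genes and transcript regions at these positions are not given, because the annotation at hand is on another genome build.

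Bases called in all 3 replicates were spread unevenly over the windows that held any. Windows without such a base were not counted, and transcript abundance was not corrected for, so the shares do not show a preference of HuR. Of 46049 10-kb windows, counted by strand, with a base called in all 3 replicates, the top 1% held 8.40% of such bases and the top 10% held 41.2%. The median window had 90 nt. The window with the most was chromosome 19:57800001-57810000 on the plus strand, with 3545 nt called in all 3 replicates, or 35.5% of its length, and 26, 22 and 24 sites in replicates 1, 2 and 3. Chromosome 2:179370001-179380000 on the plus strand followed with 3260 nt and 41, 44 and 48 sites. Chromosome 10:96360001-96370000 on the plus strand had 2965 nt, chromosome 1:162490001-162500000 on the plus strand 2900 nt and chromosome 2:75880001-75890000 on the plus strand 2860 nt. Chromosome 1:173900001-173910000 on the minus strand had 2790 nt. Of the 10 leading windows, 3 were on chromosome 19, but the leading window and chromosome 19:57810001-57820000 on the plus strand adjoin and are not separate places.

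**Figure D3:**
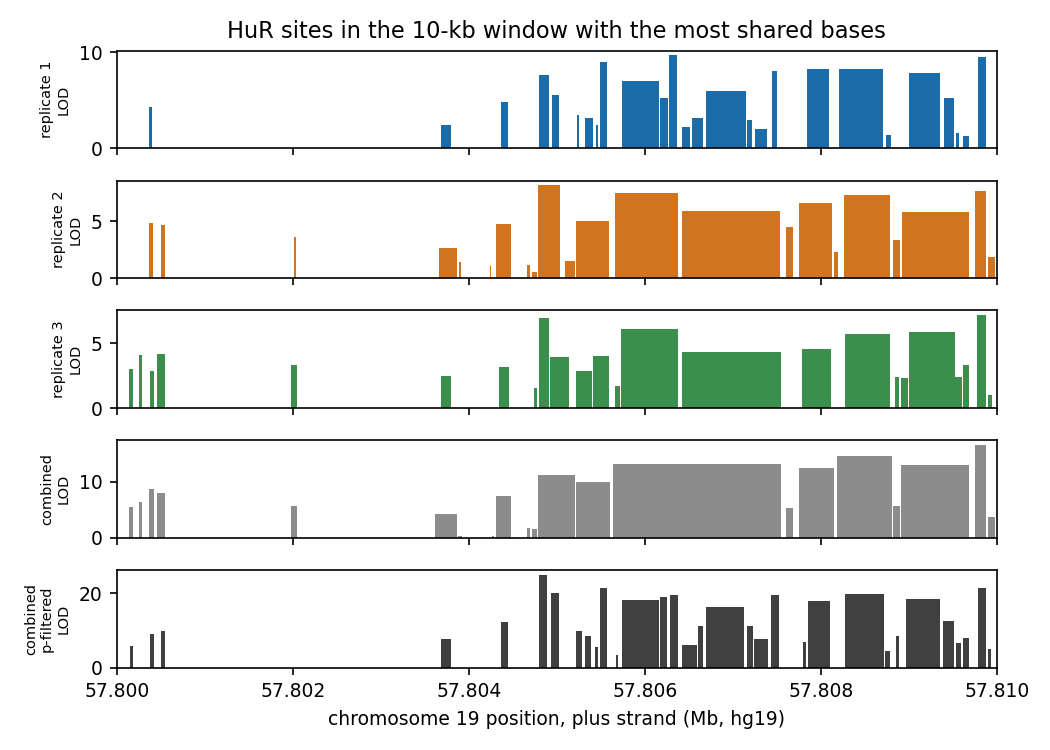
HuR sites on the plus strand of chromosome 19:57800001-57810000 (horizontal axis, Mb, hg19) in the 3 replicates, the combined list and the p-filtered combined list. Each bar spans a site and its height is the LOD score in that list, on a separate vertical scale per panel, and the sites lie mostly in the same places in all 5 panels, with 3545 nt called in all 3 replicates.

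Within a neighbourhood, most sites in these lists lay on 1 strand. In 89.9% of the 25565 10-kb windows with at least 10 combined sites, at least 90% of the sites were on the same strand, against 0.348% after strands were shuffled. In the replicates the share was 91.3% ± 0.753 (SD, n = 3). The nearest neighbouring site was on the same strand for 96.0% ± 0.804 of sites (SD, n = 3), where 50% is the value for independent strands. In 100-kb windows the share was lower, at 67.7%. Fragments of 1 transcript share its strand whatever protein is bound, so neither shuffled nor independent strands are a test of HuR. These values describe the lists only.

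Sites were spread unevenly over chromosomes in the files used here. The mitochondrial genome had 17.7 ± 7.17 times its share by length (SD, n = 3), from 23, 40 and 28 sites in replicates 1, 2 and 3. Among the numbered chromosomes, chromosome 17 had 1.95 ± 0.180 times its share (SD, n = 3) and chromosome 19 had 1.53 ± 0.205 times. Chromosome 13 had 0.618 ± 0.0479 times and chromosome 4 had 0.720 ± 0.0665 times. Of the 22 numbered chromosomes, 11 were above 1 and 10 below 1 in all 3 replicates. The ratios were not corrected for gene content, transcript abundance or the line's chromosome copy number. Length ran to the end of the last site. Stretches of the build where no site could be called counted as length, which can lower a ratio. The ranks and the counts above and below 1 therefore hold for this length only.

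**Figure D4:**
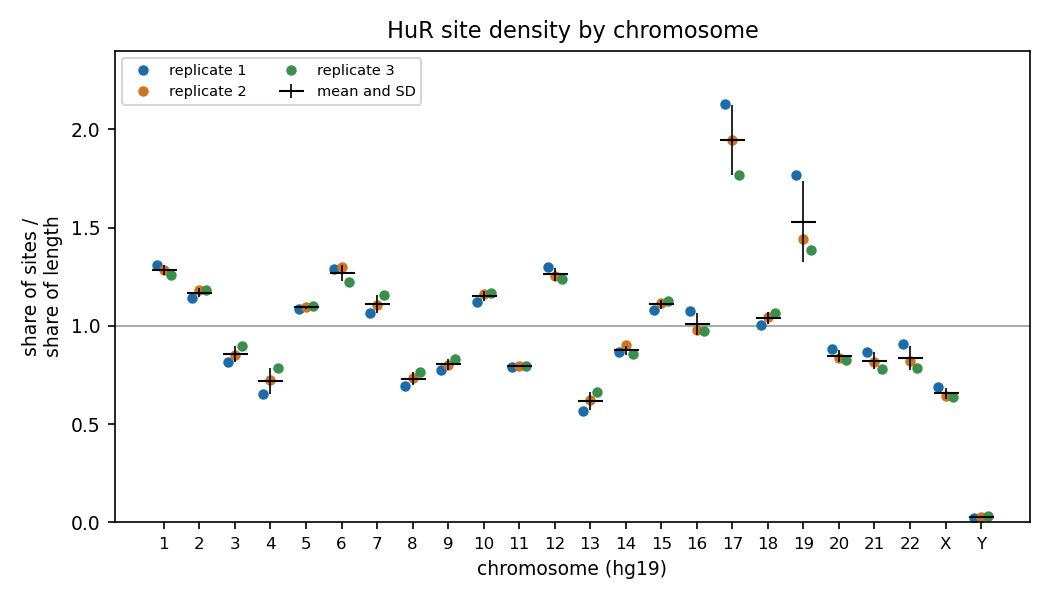
Share of HuR sites divided by share of length (vertical axis) for each nuclear chromosome (horizontal axis, the mitochondrial genome is not plotted). Length runs to the end of the last site, uncalled stretches included. Points are replicates, with the mean and SD in black. Among the chromosomes plotted, chromosome 17 is highest with a mean of 1.95, chromosome 19 follows with 1.53, and chromosome 13 is the lowest numbered chromosome with 0.618.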

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

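The alternatives for strand shares, opposite strands, score deciles and chromosome ratios were chosen after seeing the data. Of 70 alternative values for 15 results, 51 stayed within the bound set for the result, 19 moved and 0 reversed. The bound was a fixed fold ratio for site number and otherwise the spread between replicates. Without replicates it was a 95% interval for counting error only, so narrow for the bases in all 3 replicates that their moves say little. Other bounds were too wide to fail easily. For sites matched in both other replicates the spread was 32.7 points around 51.8%, so 32.7% and 74.9% counted as unmoved. Leave-one-out values also helped to set the spread they were judged by, so the count of 51 is no measure of robustness. With equal numbers of sites, pairwise overlap fell to 64.3% and the bases in all 3 replicates were 22.6%. With at least 50% of each interval shared, pairwise overlap was 67.0%. At LOD above 1 the bases in all 3 replicates were 21.6% and the share kept by the p filter 54.4%, and at LOD above 2 the former was 21.1% and the mean correlation 0.529. Without each replicate in turn, pairwise overlap ranged from 85.8% to 92.7%, the Jaccard index from 25.8% to 56.6%, bases in all remaining replicates from 25.8% to 56.6% and the correlation from 0.561 to 0.704. The value of 56.6%, against 21.8% with all 3, came without replicate 1, and leaving a replicate out also changes the definition from 3 lists to 2. In the p-filtered list, whose scores need not share the combined list's scale, the LOD difference between sites in 3 and in 1 replicates was 6.55 and the strand share 92.4%. In 100-kb windows the strand share was 67.7%, and in the combined list opposite-strand overlap was 0.928 times the shifted number. Among recurrent sites only, the ratio was 2.14 for chromosome 17 and 0.568 for chromosome 13. The cause of these moves was not tested. Unknown depth limits all statements on missing sites. Settings for transcript regions, sequence and gene lists were not run. No paired analysis was possible because the files used here hold no values for the negative control samples.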

Other observations

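Mitochondrial sites were dense for the length of that genome, at 17.7 ± 7.17 times its share (SD, n = 3), and low in score. The combined list had 57 such sites, with a median LOD of 1.64 against 6.46 elsewhere, and the replicates had 30.3 ± 8.74 (SD, n = 3). Their scores had a median percentile of 5.88 ± 3.50 within the replicate lists (SD, n = 3). Of the 57 sites, 29 were on the minus strand. All 3 replicates held 21 of the 57, 15 of these on the minus strand, and the p filter kept 17. The highest combined scores were 12.1 at M:9616-9710 and 10.4 at M:8446-8560, both on the minus strand.

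Some very high combined scores lay at sites found in fewer than 3 replicate lists. A list without a site there does not show that its library gave no reads to the combined score. Of 489 combined sites with a LOD above 22, 484 were found in all 3 replicates and 5 were not, and the p filter removed each of those 5 and 1 of the others. Chromosome 6:142105946-142105975 on the minus strand had a combined LOD of 28.8 and a site in replicate 3 alone. Chromosome 2:128607541-128607565 on the plus strand had 29.4 and sites in replicates 1 and 3. These sites were chosen after their values were seen. Sites overlapping another site on the opposite strand were fewer than after shifting, at 0.729 ± 0.0725 times the shifted number in the replicates (SD, n = 3), and 0.928 times in the combined list. Of 453 combined sites on chromosome Y, 138 had a partner on chromosome X at an offset of 50000 nt, against at most 14 at 40 other offsets. The paired sites had a median LOD of 6.93 on Y and 7.15 on X, with a median absolute difference of 1.04. The pairs were not shown to be separate sites, so counts on chromosome Y may repeat sites of chromosome X.

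Of the tests that follow, those on the overlap of replicate 1 sites with replicate 3 and on wide sites were chosen only after the result was seen, and the tests on low-scoring sites were written after that pattern, but before their own values, were seen. The number of sites differed 2.96-fold between replicates. Unequal sensitivity of the libraries is a candidate explanation: 92.1% of replicate 1 sites overlapped a replicate 3 site by at least 1 nt, and 64.0% with at least 50% of each interval shared. Replicate 3 scores separated the sites matched in replicate 1 from the others with an area under the ROC curve of 0.710, just past the bound of 0.7 set beforehand. On the other side, this pair overlapped at 55.6% with equal numbers of top-scoring sites, the lowest of the 3 pairs. Of replicate 3 sites in its top score decile, 74.3% overlapped a replicate 1 site. Whether unequal sensitivity is the whole account was not tested. Sequencing depth was not analysed here and no biological explanation was tested.

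In replicates 2 and 3, but not in replicate 1, sites of the lowest score decile overlapped both other replicates more often than those of the third decile, by 11.4 and 17.7 percentage points. For replicate 2 this rests on replicate 1, which overlapped 28.9% against 14.2%, while replicate 3 overlapped 58.6% against 75.8%. Greater width as the whole account is argued against by sites of 30 to 40 nt, where the mean difference was still 12.1 points. Chance overlap in crowded neighbourhoods (a difference of 9.98 points after a shift of 500 nt, out of a mean of 14.5) and RNA abundant enough to be recovered in the control too (2.14 more same-strand sites within 1 kb, a measure of crowding and not of abundance) may contribute and were not separated. In replicate 1 the lowest-decile sites were also more crowded (3.40 against 1.37 sites within 1 kb) and overlapped more after shifting (23.4% against 10.9%). They recurred less (65.8% against 77.4%). Chance overlap adds to any other recurrence, so this lower total does not decide against either explanation. The deciles also differ: the third of replicate 1 held its commonest score (3.984, 16549 sites), which lay in the second decile in replicates 2 and 3. No biological explanation was tested.

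The 794 combined sites over 500 nt were all found in all 3 replicates, and the widest was chromosome 19:57766436-57769125 on the plus strand, at 2690 nt. Read depth of abundant RNA, rather than wider binding, could join separate sites: the p filter split these sites into a median of 4 intervals, but wider sites have room for more intervals in any case. It kept 62.7% of their bases, between the bounds set for and against it. This was the highest share of the width classes, which kept 28.6% up to 50 nt and 58.3% from over 200 to 500 nt. The question stays open, and no biological explanation was tested.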
